A study of Mus musculus with 12 samples.

How the data were processed

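RAW264 cells are a mouse macrophage line. Per the labels' protocols, cells were left untreated (basal), given lipopolysaccharide (LPS, a bacterial cell wall component that activates macrophages) at 100 ng/ml for 30 min, or given LPS together with the glucocorticoid dexamethasone (DEX) at 10 µM for 30 min. Cycloheximide, which holds cytosolic ribosomes on mRNA, was added at 100 µg/ml before extraction. Poly(A) mRNA and ribosome-protected mRNA fragments (RPF, also called footprints) were sequenced on an Ion PGM. The aligner, the genome build and the annotation are not given in the sources used here, so no gene positions are given.

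The values deposited by the authors are read counts scaled to the total reads of a library (CPM) plus 1, per Ensembl gene and library. The unit was read from the values themselves: the lowest value is 1, and after subtracting 1 all values (100%) of every library are whole multiples of the worth of 1 read, with a tolerance of 0.1 read. There is no scaling by gene length. The 9621 listed genes each have a value above 16 in at least 1 of the 12 libraries, and they hold 97.4% to 98.9% of the reads of a library. Gene symbols came from a table of Ensembl names, which matched 9521 of the 9621 identifiers.

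Before the data were examined, the comparisons, the gene lists, the rule for named genes and most alternative settings were fixed. That design assumed read counts, and for normalized values it named limma-trend on log2(value + 1). Since the deposited value already holds an added 1, limma-trend was run on log2(CPM + 1), the log2 of the deposited value itself, and log2(CPM + 2) was run as an alternative chosen after seeing the data. R 4.3.3 and limma 3.58.1 were used. A gene was tested if it had at least 10 reads at the median depth in at least 2 libraries and at least 15 reads in total. The 6 mRNA libraries were fitted together, and so were the 6 RPF libraries, with the 3 treatment groups as the only factor. Translational efficiency (TE) is the RPF value over the mRNA value on the log2 scale. Its change between treatments is the RPF change minus the mRNA change, tested as an interaction in 1 fit over all 12 libraries, and its level in basal cells is RPF against mRNA in the same fit. Adjusted p values are Benjamini-Hochberg values over all genes tested in a comparison, two-sided, and a gene passed the test at an adjusted p under 0.05. Errors of log2 fold changes are standard errors (SE) from limma, and errors of CPM values are standard deviations (SD) over the 2 libraries of a group.

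CPM values are scaled to the total reads of a library, so each change is relative to that total. As the other scaling, libraries were scaled by the median of ratios (relative log expression). In the median over genes this lowered mRNA changes of LPS against basal by 0.26 and of LPS + DEX against basal by 0.29 (log2). It raised TE changes by a median of 0.29 and 0.32, and it lowered TE levels in basal cells by a median of 0.27. In the other comparisons the median shift was 0.06 or less. The shift was not equal for all genes: the histone median of TE for LPS against basal went from -0.94 to -0.82.

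The gene lists were immediate early genes, NF-kB targets and inhibitors, cytokines and chemokines, interferon response, MAPK feedback, glucocorticoid induced genes, ribosomal proteins, other TOP mRNAs, nuclear genes of oxidative phosphorylation, mitochondrially encoded genes, integrated stress response, ER chaperones, cytosolic heat shock proteins, replication-dependent histones, macrophage markers, other cell types, cell cycle, cholesterol synthesis, glycolysis and translation initiation factors. Of these 20 lists, 19 had enough listed genes for a test. Lists were tested with limma's camera, which compares the members with all other genes at a preset inter-gene correlation of 0.01, and again with a correlation estimated from the data. Of the 190 list tests (19 lists in 10 comparisons), 77 passed with the preset correlation and 4 with an estimated one. Those 4 are the ribosomal proteins in the TE changes of LPS and of LPS + DEX against basal, and the ribosomal proteins and histones in the TE level of basal cells.

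Named genes were chosen by a rule: per comparison, the 10 highest and the 10 lowest log2 fold changes among genes that passed, whose groups did not overlap and whose higher group had a mean of at least 10 reads. A set of 18 genes chosen in advance was added for every comparison (Il1b and Egr1 of that set are not among the listed genes and are not analysed here), and the 4 members of each list with the largest change among those that passed. Genes outside the rule are named as chosen after their values were seen. Where the libraries of a group lie at or under 3 reads, CPM values are given and no fold. The value of 3 reads was 1.19 to 3.65 CPM over the 12 libraries. The protocols describe no molecular identifiers for reads, so limits set by read numbers cover counting error alone. Histone genes, pseudogenes and the Bcl2a1 family share sequence with their relatives, so which copy a read came from is uncertain.

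As a self-test, known changes were put into simulated libraries of the same depth, with a spread per group that leaves out the most variable genes and has a lower limit of 3.16%. Real genes can vary more, so the shares recovered are upper values. At a 4-fold change limma recovered 97% of the altered genes in each mRNA comparison, 92% to 98% in the RPF comparisons and 78% to 84% in the TE comparisons. At a 2-fold change it recovered 59% to 65%, 66% to 76% and 27% to 33%. It made 0 to 16 false calls per comparison.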

Results

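mRNA abundance and ribosome footprints were measured in RAW264 macrophages without treatment, after 30 min of LPS, and after 30 min of LPS + DEX. Each of the 6 groups (3 treatments in 2 assays) holds 2 independent biological replicates, which makes 12 libraries. The mRNA libraries held 1475119 and 1847359 reads (basal), 1692014 and 2276336 (LPS), and 2529666 and 2256872 (LPS + DEX), in the order of the replicate numbers. The RPF libraries held 1310291 and 1520613 (basal), 829415 and 821946 (LPS), and 1653342 and 1833558 (LPS + DEX). Spearman correlations across genes were 0.94 to 0.983 among RPF libraries and 0.894 to 0.98 among the mRNA libraries other than basal replicate 1. The mRNA library of basal replicate 1 stood apart, at 0.781 to 0.831 with the other mRNA libraries. In it, 81 genes had at least 50 CPM while staying at or under 5 CPM in the other 5 mRNA libraries, among them the keratin Krt7 (1110 CPM), the collagen receptor Ddr1 (923 CPM) and renin, Ren1 (402 CPM). These were chosen after their values were seen. Genes are not independent replicates, so these correlations carry no p.

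Comparing mRNA after LPS with basal mRNA asks which transcripts respond within 30 min. LPS raised mRNAs of cytokines, chemokines, immediate early transcription factors and feedback inhibitors of NF-kB. Tnf mRNA (ENSMUSG00000024401), which encodes the inflammatory cytokine TNF, rose from 83.8 ± 5.44 to 1180 ± 332 CPM (mean ± SD, n = 2), a log2 fold change of 3.78 ± 0.21 (SE, adjusted p = 0.00145). The neutrophil chemokine Cxcl2 (ENSMUSG00000058427) rose from 7.58 ± 6.89 to 210 ± 55.7 CPM, a log2 fold change of 4.88 ± 0.52. Nfkbiz, an atypical IkB protein, rose by 3.89 ± 0.36 (log2) and the AP-1 subunit Jun by 3.28 ± 0.27. The immediate early gene Ier2 rose by 3.48 ± 0.34, and Ppp1r15a, which directs dephosphorylation of the initiation factor eIF2, by 3.34 ± 0.23. Cxcl3, another neutrophil chemokine, went from 0.541 ± 0.766 CPM, under the value of 3 reads, to 23 ± 11.6 CPM. Limma called 838 genes higher and 156 lower of 9277 tested. With median-of-ratios scaling the split turned to 190 higher and 332 lower, so the balance of directions depends on the scaling. The calls also rest on both LPS libraries, and few passed without either one. Such a fit takes its spread from fewer libraries, basal replicate 1 among them, so a lost call does not show that a change was absent. In these fits 0 of the 994 genes changed sign. Tnf, Nfkbiz and Jun measured 4.07, 4.49 and 3.74 (log2) without mRNA LPS replicate 1, and 3.49, 3.29 and 2.82 without replicate 2. Without basal replicate 2, more genes passed, but the basal group then holds only replicate 1, the library that stood apart.

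The lists show which groups of mRNAs moved, among the members that are listed at all. Of 27 immediate early genes, 15 rose and none fell (18 rose adjusted over the list alone), with a median log2 fold change of 1.4 (limma's camera, adjusted p = 9.93e-09, adjusted p = 0.42 with an estimated correlation). Of 14 cytokine and chemokine genes, 8 rose (9 adjusted over the list alone; camera adjusted p = 0.000286, adjusted p = 0.412 with an estimated correlation), including the chemokines Ccl4 (1.85 ± 0.19) and Ccl3 (1.46 ± 0.15). NF-kB targets and inhibitors rose in 7 of 33 cases (10 adjusted over the list alone; camera adjusted p = 0.00404, adjusted p = 0.42 with an estimated correlation), among them Tnfaip3, an inhibitor of NF-kB signalling also called A20 (2.75 ± 0.33), and Nfkbia, which encodes IkBα (1.96 ± 0.2). MAPK feedback genes rose in 4 of 13 cases, and in 1 with median-of-ratios scaling (7 adjusted over the list alone; camera adjusted p = 0.0285, adjusted p = 0.42 with an estimated correlation). The MAPK phosphatase Dusp1 measured 0.71 ± 0.47 and did not pass (adjusted p = 0.336), but without mRNA basal replicate 1 it measured 1.54 ± 0.24 and passed (adjusted p = 0.00159), and without basal replicate 2 it measured -0.13. Nor did the glucocorticoid targets Per1 (1.01 ± 0.32, adjusted p = 0.0817) and Fkbp5 (0.17, adjusted p = 0.605) pass. Without mRNA LPS replicate 1 the calls of Cxcl2, Zfp36, Fos, Ccl3, Ccl4 and Ptgs2 were lost, and without replicate 2 those of Tnfaip3, Nfkbia and Ier3 as well.

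Some mRNAs of ribosomal proteins and of the respiratory chain were lower after LPS. Of 79 ribosomal protein mRNAs, 35 fell and none rose (55 fell adjusted over the list alone), with a median of -0.45. With median-of-ratios scaling 60 fell at a median of -0.72 (camera adjusted p = 1.07e-41, adjusted p = 0.289 with an estimated correlation). Rpl30 measured -0.89 ± 0.14 and Rpl26 -0.83 ± 0.1. Of 74 nuclear mRNAs of oxidative phosphorylation, 16 fell and 2 rose (30 and 4 adjusted over the list alone), with a median of -0.34, and with median-of-ratios scaling 32 fell and 0 rose (camera adjusted p = 3.66e-17, adjusted p = 0.289 with an estimated correlation), among them the complex I subunit Ndufa5 (-1.12 ± 0.21). The largest fall under the naming rule was that of Pin4, a peptidyl-prolyl isomerase (-1.44 ± 0.3, adjusted p = 0.0296). No ribosomal protein or oxidative phosphorylation mRNA kept its call without mRNA LPS replicate 1 (13 genes called in all) or without replicate 2 (6 genes).

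The RPF comparison of LPS with basal cells asks which mRNAs gained or lost ribosomes over the same 30 min. Footprints rose on Tnf, Cxcl2 and other cytokine and immediate early mRNAs, and on mt-Co1 and other mitochondrially encoded mRNAs. Tnf footprints rose from 53.4 to 1270 CPM (log2 fold change 4.55 ± 0.13, adjusted p = 2.65e-11). Those of Cxcl2 rose by 4.95 ± 0.23 (log2), of Nfkbiz by 3.45 ± 0.22, of the immediate early gene Ier3 by 3.42 ± 0.19, and of Zfp36, which promotes decay of cytokine mRNAs, by 3.22 ± 0.38. Dusp1 footprints rose by 1.34 ± 0.23 (adjusted p = 0.00302), and the TE test did not separate this from its mRNA change (0.63 ± 0.54, adjusted p = 0.451). On the lower side, footprints of Nob1 (ENSMUSG00000003848), an endonuclease that matures 18S rRNA, fell from 482 to 87.8 CPM (-2.45 ± 0.12, adjusted p = 2.23e-08). Its mRNA measured 73.2 CPM in basal cells and 97.2 CPM after LPS, and its TE fell by 2.85 ± 0.19 (adjusted p = 1.32e-05). Footprints of the mitotic and apoptosis regulator Birc5 measured -1.39 ± 0.15. Limma called 292 genes higher and 382 lower of 8847. Median-of-ratios scaling gave 385 higher and 277 lower, so which direction holds more genes depends on the scaling. Without RPF LPS replicate 1, 375 genes passed, and without replicate 2, 394.

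Cytokine and chemokine footprints rose in 9 of 13 cases (9 adjusted over the list alone; camera adjusted p = 3.81e-14, adjusted p = 0.104 with an estimated correlation), and immediate early footprints in 11 of 27 (11 adjusted over the list alone; camera adjusted p = 8.02e-10, adjusted p = 0.104 with an estimated correlation). Of 13 mitochondrially encoded genes, 12 rose (12 adjusted over the list alone), with a median of 1.44 (camera adjusted p = 8.84e-25, adjusted p = 0.104 with an estimated correlation). The complex I subunit mt-Nd3 rose by 1.94 ± 0.15 and the cytochrome oxidase subunit mt-Co1 by 1.61 ± 0.15. Ribosomal protein footprints rose in 22 of 79 cases and fell in 7, or in 31 and 4 with median-of-ratios scaling (37 and 13 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 4.25e-08, adjusted p = 0.199 with an estimated correlation). Rpl39 rose by 0.82 ± 0.13 and Rps2 measured -0.7 ± 0.1. Replication-dependent histones fell in 34 of 59 cases and rose in none (45 adjusted over the list alone), with a median of -0.48 (camera adjusted p = 1.17e-19, adjusted p = 0.448 with an estimated correlation). Their reads are shared between nearly identical copies, so single histone genes are uncertain.

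**Figure D1:**
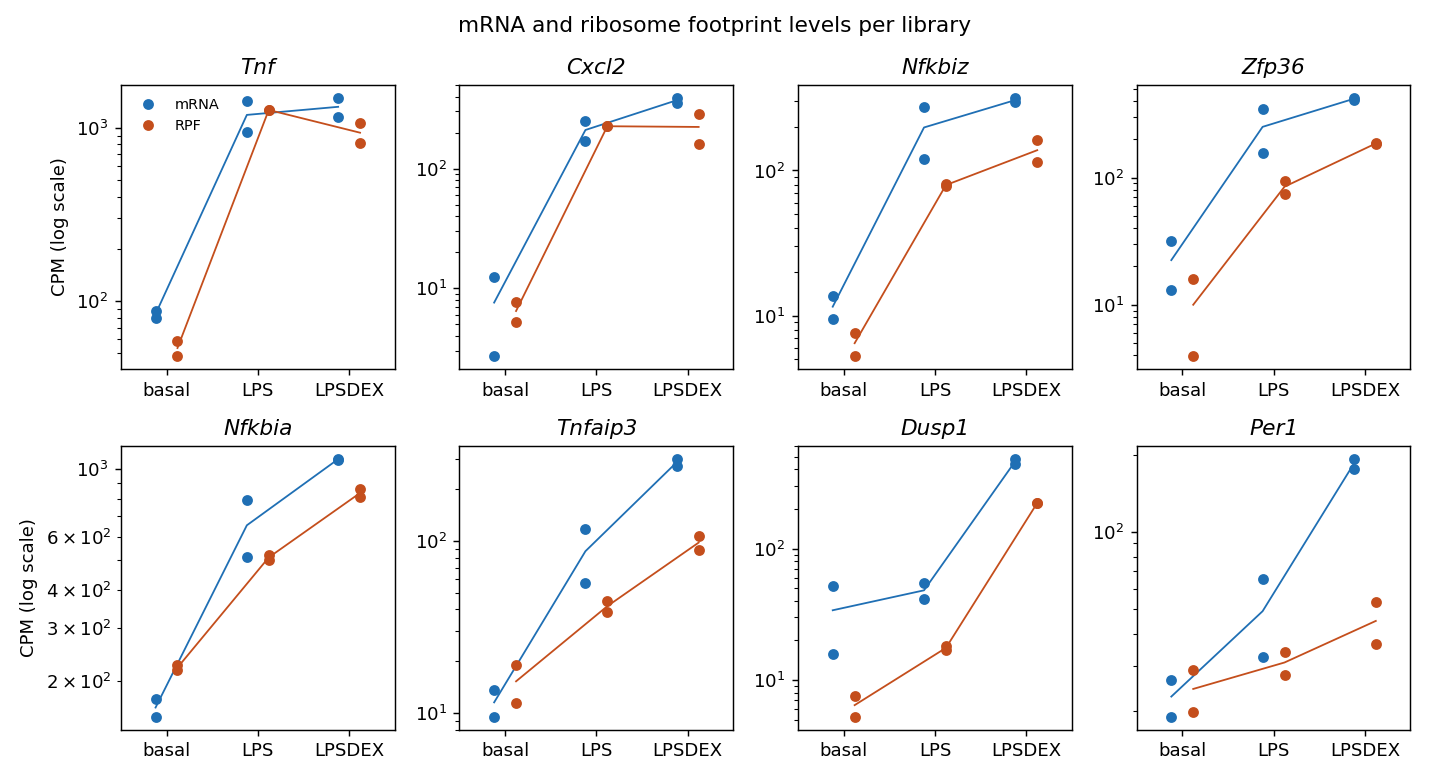
CPM (log axis) of 8 genes in each mRNA and RPF library, by treatment; points are libraries (2 per group) and lines join the group means. Tnf and Cxcl2 are high in all LPS and LPS + DEX libraries, and Dusp1 reaches 462 ± 30.2 CPM of mRNA with LPS + DEX against 48.1 ± 9.58 with LPS.

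Setting the mRNA and footprint changes side by side asks how far ribosome occupancy follows transcript abundance. Tnf, Cxcl2, Nfkbiz, Zfp36 and Ier3 rose in both assays. Across all genes the assays did not run together: over 8697 genes the changes of LPS against basal had a Pearson correlation of 0 and a Spearman correlation of -0.14, and 40.9% had the same sign. The same-sign share can depend on the scaling. The median change was 0.26 in mRNA and -0.07 in RPF, against 0.01 and -0.01 with median-of-ratios scaling. Neither the share with that scaling nor a correlation without mRNA basal replicate 1 was computed. Of 129 genes that passed in both assays, 33 were higher in both (24.4 by chance), 11 lower in both (6.22 by chance), and 85 moved in opposite directions (37.2 by chance; 79 and 18.6 with median-of-ratios scaling). The 85 rest on both mRNA LPS libraries, since nearly all lost their mRNA call without either one, though 0 of the 994 mRNA calls changed sign. Many of the 85 were also lost without RPF LPS replicate 1, RPF LPS replicate 2 or RPF basal replicate 2. Genes higher in mRNA and lower in footprints included Rela, the p65 subunit of NF-kB (mRNA 1.42, RPF -0.75, TE -2.17), the calcium channel Orai1 (1.74, -0.94 and -2.69) and Actb, or β-actin (1.36, -0.33 and -1.69). Genes lower in mRNA and higher in footprints included the actin-binding thymosin Tmsb4x (mRNA -0.85, RPF 1.08, TE 1.93) and Rps15a (-0.75, 0.69 and 1.44). These genes were chosen after their values were seen. A difference in preparation between basal and treated mRNA libraries, left open below for ribosomal protein mRNAs, is open for the mRNA changes and TE of the 85 genes too.

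**Figure D2:**
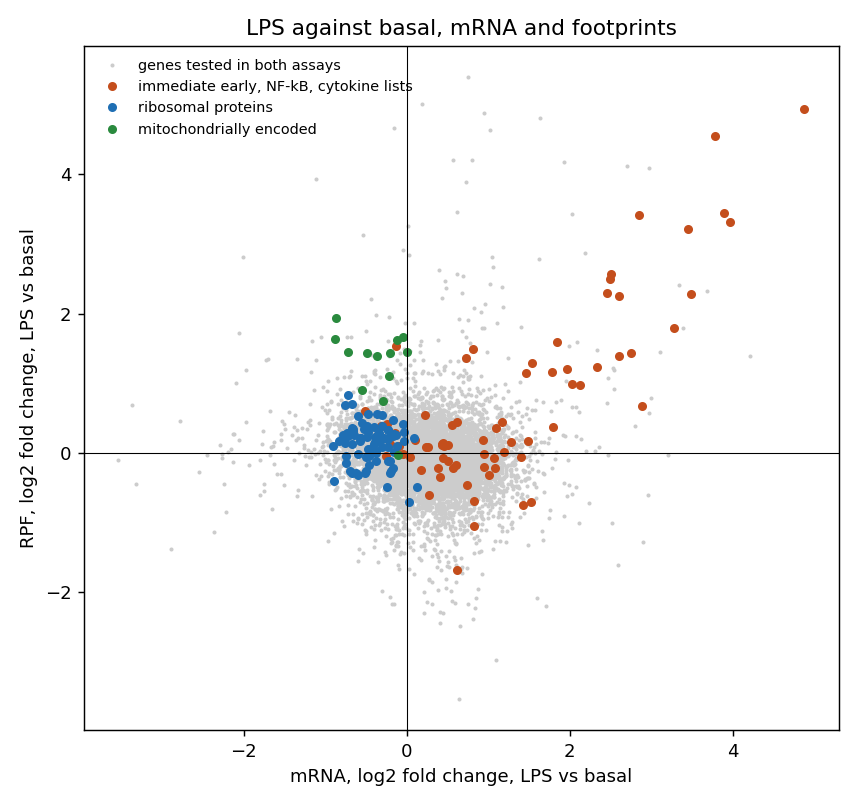
log2 fold change of RPF (vertical) against that of mRNA (horizontal) for LPS against basal, 1 point per gene, with lists coloured. Tnf, Cxcl2 and other inflammatory genes lie at the upper right, but members of these lists such as Rela (mRNA 1.42, RPF -0.75) lie at the lower right. Ribosomal proteins lie mostly left of 0 on the mRNA axis (median -0.45, -0.72 with median-of-ratios scaling), and mitochondrially encoded genes mostly above 0 on the RPF axis (median 1.44).

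The TE test asks whether the footprint change differs from the mRNA change. TE of ribosomal protein mRNAs rose: 46 of 79 were higher and 2 lower (58 and 2 adjusted over the list alone), with a median of 0.52, or 0.82 with median-of-ratios scaling. This list passed with either correlation (camera adjusted p = 1.66e-42, adjusted p = 0.0321 with an estimated correlation), and Rps15a rose by 1.44 ± 0.14. The lower mRNA (median -0.45) made up more of this TE rise than the footprints (median 0.17). A difference in preparation between basal and treated mRNA libraries, left open below for the mRNA fall, is therefore open for this TE rise too. TE of mitochondrially encoded mRNAs rose in 11 of 13 cases (12 adjusted over the list alone; camera adjusted p = 8.49e-15, adjusted p = 0.279 with an estimated correlation). TE of oxidative phosphorylation mRNAs was higher in 17 of 74 cases and lower in 8, or in 29 and 1 with median-of-ratios scaling (22 and 11 adjusted over the list alone; camera adjusted p = 1.48e-08, adjusted p = 0.201 with an estimated correlation), with Uqcr10 at 1.42 ± 0.2. Lower TE was measured for Rela (-2.17 ± 0.29), for the transcription factor Srf (-2.24 ± 0.37), for the translocon subunit Sec61a1 (-1.55 ± 0.18) and for the receptor Csf1r (-1.12 ± 0.17). A difference in preparation of the mRNA libraries is open for these values too. Tnf TE measured 0.77 ± 0.27 and did not pass (adjusted p = 0.0635). Limma called 290 genes higher and 1277 lower of 9412, and median-of-ratios scaling gave 558 higher and 501 lower, so the excess of lower genes depends on the scaling. Without mRNA LPS replicate 2, 736 genes passed, and without RPF basal replicate 2, 820.

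Comparing LPS + DEX with LPS asks what the glucocorticoid changes within 30 min of a shared LPS stimulus. In footprints, DEX raised the feedback phosphatase Dusp1 and the NF-kB inhibitors Nfkbia and Tnfaip3, and it lowered mitochondrially encoded genes. Dusp1 footprints (ENSMUSG00000024190) rose from 17.6 to 222 CPM (3.59 ± 0.23, adjusted p = 3.68e-07), those of Nfkbia from 512 to 836 CPM (0.71 ± 0.09, adjusted p = 0.000269), and those of Tnfaip3 by 1.21 ± 0.24 (adjusted p = 0.00755). Tnf footprints fell from 1270 to 935 CPM (-0.45 ± 0.13, adjusted p = 0.0485). Footprints of Nos2, the inducible nitric oxide synthase, fell from 40.6 ± 16.5 to 3.42 ± 0.561 CPM (-3.18 ± 0.43), and those of the interleukin 1 receptor antagonist Il1rn from 190 ± 2.93 to 59.9 ± 6 CPM (-1.65 ± 0.15). Their TE changes did not pass (Nos2 -3.79, adjusted p = 0.0598, and Il1rn -0.84, adjusted p = 0.838). Per1 and Fkbp5, further known glucocorticoid targets, measured 0.51 (adjusted p = 0.288) and -0.23, and Cxcl2 measured -0.07. Tsc22d3, also a known target, had 2.41 and 2.43 CPM with LPS, under the value of 3 reads, and 6.65 and 7.63 CPM with LPS + DEX. This difference did not pass, and with LPS + DEX its footprints stayed under those of basal cells (9.92 and 15.1 CPM). Limma called 278 genes higher and 314 lower of 8847. Without RPF LPS + DEX replicate 1, 169 genes passed, without replicate 2, 103, without RPF LPS replicate 2, 296, and without LPS replicate 1, 317. The Tnf call was lost without any of these 4 libraries (-0.26 without LPS + DEX replicate 2) and the Tnfaip3 call without each but LPS replicate 2, while those of Dusp1, Nfkbia, Nos2 and Il1rn held without each.

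All 13 mitochondrially encoded genes fell in footprints with DEX (13 adjusted over the list alone), with a median of -2.15 (camera adjusted p = 1.7e-39, adjusted p = 0.216 with an estimated correlation). The complex I subunit mt-Nd1 measured -2.76 ± 0.18, cytochrome b (mt-Cytb) -2.41 ± 0.14 and mt-Atp6 -2.34 ± 0.1. ER chaperones and translocon subunits fell in 8 of 27 cases and rose in none (13 adjusted over the list alone; camera adjusted p = 4.45e-08, adjusted p = 0.223 with an estimated correlation), among them Ssr3 (-0.74 ± 0.11). Integrated stress response genes fell in 3 of 22 cases (4 adjusted over the list alone; camera adjusted p = 0.000565, adjusted p = 0.294 with an estimated correlation). MAPK feedback genes rose in 3 of 13 cases, Dusp1, Dusp2 and Dusp6 (3 adjusted over the list alone), though the list median was -0.17. Of these 3, Dusp2 lost its call without any of the 4 libraries (adjusted p = 0.0146 with all) and Dusp6 without each but LPS replicate 2. Cholesterol synthesis had 1 member higher and 1 lower of 20, the same numbers adjusted over the list alone, and a median of 0.3 (camera adjusted p = 0.0143, adjusted p = 0.294 with an estimated correlation). The cytokine and chemokine list had 3 of 13 members lower (3 adjusted over the list alone; camera adjusted p = 0.0663). Among nuclear genes of oxidative phosphorylation, 5 rose and 6 fell of 74 (6 and 10 adjusted over the list alone), with the complex I subunit Ndufb7 at 1.31 ± 0.13 and the complex II subunit Sdhb at 1.11 ± 0.11.

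**Figure D3:**
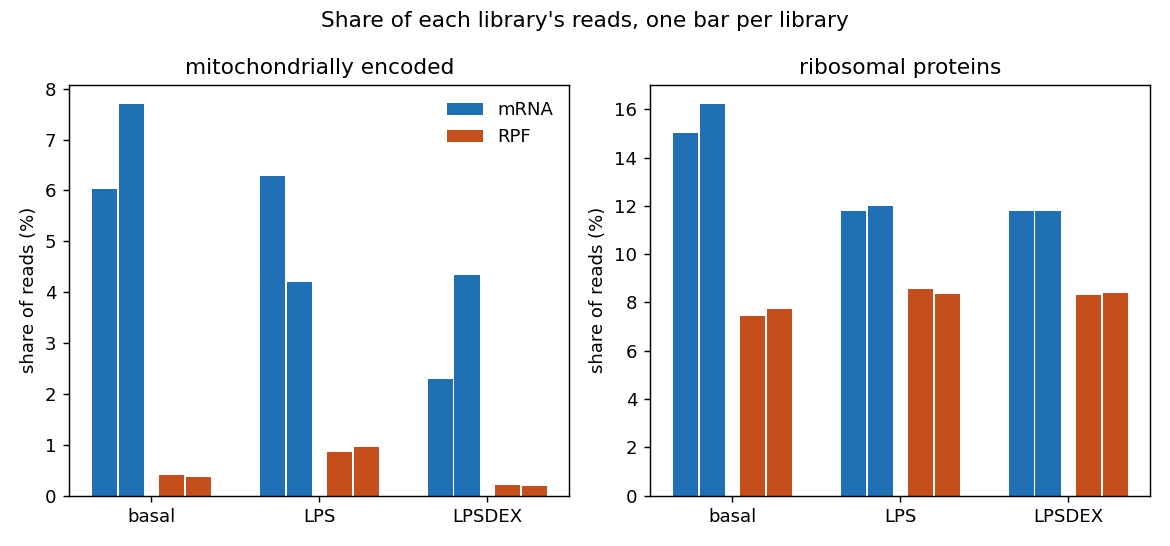
Share of all reads (%) in each library, 2 per group, for the mitochondrially encoded genes and the ribosomal proteins. Mitochondrial footprints take 0.411% and 0.365% in basal, 0.868% and 0.948% in LPS and 0.217% and 0.19% in LPS + DEX libraries, and ribosomal protein mRNAs take 15% and 16.2% in basal libraries and 11.8% to 12% after treatment.

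In mRNA, Dusp1 measured 48.1 ± 9.58 CPM with LPS and 462 ± 30.2 CPM with LPS + DEX (3.25 ± 0.47, adjusted p = 1), Per1 49 ± 23.3 and 184 ± 12 CPM (1.97 ± 0.32), Tnfaip3 1.8 ± 0.33, Nfkbia 0.76 ± 0.2 and Tnf 0.17 ± 0.21. Limma called 0 of 9277 genes, with 183 at an unadjusted p under 0.05, and limma-voom on the reads recovered from the values also called 0. The spread that decides these calls is shared with mRNA basal replicate 1, the library that stood apart. Without it, in a fit chosen after seeing the data, 5 genes passed, all higher: Dusp1 (adjusted p = 3.71e-08), Per1 (adjusted p = 0.00172), Tnfaip3 (adjusted p = 0.00347), the proteoglycan Sdc4 (1.34 ± 0.2, adjusted p = 0.00481) and B4galt4 (4.46 ± 0.58, adjusted p = 0.00172). With the LPS and LPS + DEX libraries alone the same 5 and the chemokine receptor homologue Ccrl2 (1.44 ± 0.24, adjusted p = 0.0195) passed. Sdc4, B4galt4 and Ccrl2 were chosen after their values were seen, and B4galt4 mRNA also varied within groups (0 and 152 CPM in the basal libraries). As lists, immediate early genes had a median of 0.49 (camera adjusted p = 1e-06, adjusted p = 0.587 with an estimated correlation), glucocorticoid induced genes 0.31 (camera adjusted p = 0.00125, adjusted p = 0.575 with an estimated correlation; 3 of 21 passed adjusted over the list alone, 0 over all genes) and mitochondrially encoded genes -0.67 (camera adjusted p = 9.71e-13, adjusted p = 0.585 with an estimated correlation). The mitochondrial median was -0.24 without mRNA LPS + DEX replicate 1, -1.13 without replicate 2, and -0.37 without mRNA LPS replicate 1, and the groups overlap in the share of reads (6.28% and 4.21% with LPS, 2.3% and 4.33% with LPS + DEX). The immediate early share of reads also overlapped between the groups, at 0.223% and 0.399% with LPS and 0.426% and 0.389% with LPS + DEX. ER chaperones measured -0.17 (camera adjusted p = 3.05e-06, adjusted p = 0.585 with an estimated correlation).

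Few TE changes between LPS + DEX and LPS passed the test. Limma called 1 gene higher, the respiratory chain subunit Sdhb (1.17 ± 0.15, adjusted p = 0.0186), and 4 lower: the GABA receptor subunit Gabre (-3.68 ± 0.51), the unnamed gene Gm20594 (-3.36), the muscle protein Ttn (-1.92) and the adaptor Dok1 (-1.85 ± 0.26). There were 597 genes at an unadjusted p under 0.05 and 0 called by limma-voom. The number was 0 to 12 over the fits without 1 library of the groups compared (12 without mRNA LPS + DEX replicate 1, 3 without RPF LPS replicate 1, 2 without RPF LPS + DEX replicate 1, 1 without mRNA LPS + DEX replicate 2, and 0 without each of the other 4). It was 52 (13 higher and 39 lower) without mRNA basal replicate 1, in the fit chosen after seeing the data, and 71 with only the libraries of the groups compared. The difference between the footprint and the mRNA change was 0.34 ± 0.54 for Dusp1 (adjusted p = 0.993), -0.05 ± 0.22 for Nfkbia (adjusted p = 0.998), -0.59 ± 0.44 for Tnfaip3 (adjusted p = 0.938) and -0.62 ± 0.27 for Tnf (adjusted p = 0.717), so a difference between the assays was not shown for them. As a list, mitochondrially encoded genes had a median TE change of -1.51 (camera adjusted p = 8.64e-21, adjusted p = 0.426 with an estimated correlation), with 0 of 13 passing over all genes and 12 lower adjusted over the list alone. Across 8697 genes, mRNA and RPF changes had a Pearson correlation of 0.22 and the same sign in 60.4% of cases.

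Most footprints that LPS had changed went in the opposite direction on adding DEX. Of the 292 genes with higher footprints after LPS, 84.6% were lower with DEX (median -0.48), against 65.4% (median -0.05) in simulations where DEX does nothing and the LPS libraries are shared. Of the 382 with lower footprints after LPS, 82.7% were higher with DEX (median 0.38), against 70.8% (median 0.1) simulated. Genes called against the direction of LPS numbered 126 and 112, and genes called in its direction 4 and 13. Some passed beyond basal, as mt-Atp6 did, which rose by 0.91 with LPS and lay at -1.44 against basal with LPS + DEX. Of the 13 mitochondrially encoded genes, 12 were among the first set, and Sdhb, Ndufb7 and Birc5 (1.06 ± 0.15) among the second. In mRNA, of the 838 genes raised by LPS 24.7% were lower with DEX (median 0.13), against 58.8% simulated, and of the 156 LPS-lowered genes 25.6% were higher (median -0.07), against 58.9% simulated. The mRNA set of 838 became 190 genes with median-of-ratios scaling, 13 without mRNA LPS replicate 1 and 6 without replicate 2. The simulations numbered 50, and they called more genes than the data did (875 and 1197.1 in footprints, 2598.8 and 1020 in mRNA), so their spread is smaller and their sets do not match. Since the LPS libraries enter both contrasts, noise in them gives a reversal that these simulations may set too low. A property shared by both RPF LPS libraries, which held the fewest reads (829415 and 821946), would give a reversal too. The simulations do not cover this, and the design cannot tell it apart from an LPS change undone by DEX.

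Comparing LPS + DEX with basal cells asks what the combined treatment does from rest. Cxcl2, Nfkbiz, Tnf and other inflammatory and immediate early mRNAs were raised, and Dusp1 and Per1 were among the raised mRNAs. Cxcl2 mRNA rose by 5.72 ± 0.52 (log2), Nfkbiz by 4.63 ± 0.36, Tnfaip3 by 4.55 ± 0.33, Dusp1 by 3.96 ± 0.47 (adjusted p = 0.00611), Tnf by 3.95 ± 0.21, Sdc4 by 3.14 ± 0.22 and Per1 by 2.98 ± 0.32 (adjusted p = 0.0058). Among 27 immediate early genes, 20 rose (25 adjusted over the list alone; camera adjusted p = 5.32e-10, adjusted p = 0.382 with an estimated correlation), and among 21 glucocorticoid induced genes 6 rose (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.111). Ribosomal protein mRNAs fell in 48 of 79 cases and rose in none (54 adjusted over the list alone), with a median of -0.48, or -0.78 with median-of-ratios scaling (camera adjusted p = 1.66e-33, adjusted p = 0.289 with an estimated correlation). Mitochondrially encoded mRNAs fell in 6 of 13 cases, and in 10 with median-of-ratios scaling (10 adjusted over the list alone; camera adjusted p = 2.91e-09, adjusted p = 0.382 with an estimated correlation), mt-Co2 measuring -1.55 ± 0.3. Limma called 1714 genes higher and 392 lower of 9277, and median-of-ratios scaling gave 708 and 837, so the balance depends on the scaling. Without mRNA LPS + DEX replicate 1 only Tnf passed (3.77 ± 0.24, adjusted p = 0.0494), and without replicate 2, 893 genes passed.

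Footprints of LPS + DEX against basal rose for Dusp1 (4.92 ± 0.23, adjusted p = 1.02e-08), Cxcl2 (4.87 ± 0.23), Zfp36 (4.35 ± 0.38), Nfkbiz (4.22 ± 0.22), Tnf (4.1 ± 0.13) and Fos (3.48 ± 0.34). Immediate early footprints rose in 9 of 27 cases (13 adjusted over the list alone; camera adjusted p = 4.79e-14, adjusted p = 0.0599 with an estimated correlation), and cytokine and chemokine footprints rose in 7 of 13 and fell in 2 (8 and 2 adjusted over the list alone; camera adjusted p = 1.04e-08, adjusted p = 0.128 with an estimated correlation). Mitochondrially encoded footprints fell below basal in 9 of 13 cases (11 adjusted over the list alone), with a median of -0.64, or -0.42 without RPF basal replicate 1 (camera adjusted p = 4.01e-14, adjusted p = 0.128 with an estimated correlation). Histone footprints fell in 28 of 59 cases (42 adjusted over the list alone; camera adjusted p = 2.72e-23, adjusted p = 0.227 with an estimated correlation). ER chaperones fell in 5 of 27, or in 3 with median-of-ratios scaling (10 adjusted over the list alone; camera adjusted p = 2.2e-07, adjusted p = 0.128 with an estimated correlation). Footprints of the stress response factor Atf4 measured -1.01 ± 0.18, a call lost without either RPF LPS + DEX library. Limma called 157 genes higher and 253 lower, and median-of-ratios scaling gave 197 and 191, which removes the excess of lower genes. Without RPF LPS + DEX replicate 1, 108 genes passed, and without replicate 2, 100.

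TE of LPS + DEX against basal was higher for ribosomal protein mRNAs, in 49 of 79 cases with 1 lower (65 and 1 adjusted over the list alone), at a median of 0.61 (camera adjusted p = 6.75e-52, adjusted p = 0.0189 with an estimated correlation). The mRNA median was -0.48 and the footprint median 0.15, so a difference in preparation of the mRNA libraries is open here too. TE of Sdc4 (-2.76 ± 0.27), Per1 (-2.13 ± 0.44, adjusted p = 0.00879) and Ppp1r15a (-2.05 ± 0.4) was lower, since their mRNA rose by more than their footprints. Integrated stress response genes were lower in 9 of 24 cases, and in 4 with median-of-ratios scaling (10 adjusted over the list alone; camera adjusted p = 0.00327, adjusted p = 0.463 with an estimated correlation). Glycolysis genes were lower in 6 of 16 cases at a median of -0.47, but in 1 case at a median of -0.14 with median-of-ratios scaling (8 adjusted over the list alone; camera adjusted p = 0.00327, adjusted p = 0.463 with an estimated correlation). Over 8697 genes, mRNA and RPF changes had a Pearson correlation of 0.22, and of 141 genes that passed in both assays 77 were higher in both (28.4 by chance), 25 lower in both (9.6 by chance) and 39 opposite (47.2 by chance). Leaving out mRNA LPS + DEX replicate 1 or RPF LPS + DEX replicate 1 removed nearly all of the 39. Leaving out RPF basal replicate 1 brought the number above that given by chance. Limma called 252 genes higher and 1149 lower of 9412, and median-of-ratios scaling gave 506 and 358, which turns the balance. The number was 546 without RPF LPS + DEX replicate 1, 718 without replicate 2, 719 without mRNA LPS + DEX replicate 1, 757 without RPF basal replicate 2 and 836 without RPF basal replicate 1.

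The TE level in basal cells asks which mRNAs carry more or fewer footprints per mRNA read before any stimulus, relative to the average of each assay. mRNAs of ribosomal proteins, ferritin and the mitochondrial genome carried few footprints, and most mRNAs of cell cycle, cholesterol synthesis and glycolysis genes carried many. All 79 ribosomal protein mRNAs were lower (79 adjusted over the list alone), with a median of -1.08 (camera adjusted p = 2.47e-43, adjusted p = 0.0252 with an estimated correlation), Rplp1 lying at -2.61 ± 0.09. The iron storage subunits Fth1 and Ftl1, chosen after their values were seen, measured -4.98 and -5.03. Of 13 mitochondrially encoded genes, 12 were lower (12 adjusted over the list alone; camera adjusted p = 7.25e-14, adjusted p = 0.192 with an estimated correlation), with mt-Nd1 at -6.04 ± 0.29. Cycloheximide acts on cytosolic ribosomes and mitochondrial footprints can differ in length, so these levels may not compare with those of cytosolic mRNAs. The stress response mRNAs Atf4 (-2.87 ± 0.13) and Ppp1r15a (-3.22 ± 0.28) were lower too, as was Dusp1 (-2.02 ± 0.38, or -1.18 without mRNA basal replicate 1 and -2.86 without replicate 2). Of the stress response list, 13 of 24 members were higher and 4 lower (9 and 5 with median-of-ratios scaling; 13 and 4 adjusted over the list alone; camera adjusted p = 0.269). Higher levels were measured for the proliferation marker Mki67 (2.68 ± 0.17), hexokinase Hk2 (2.76 ± 0.2), the ER proteins Sec61a1 (2.88 ± 0.13) and Canx (2.87 ± 0.13), and Hmgcs1, an enzyme of cholesterol synthesis (2.46 ± 0.26). The ER chaperone list was mixed, with 16 of 27 members higher and 7 lower, or 13 and 8 with median-of-ratios scaling (16 and 7 adjusted over the list alone; camera adjusted p = 0.0285, adjusted p = 0.406 with an estimated correlation).

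Cell cycle genes had a higher TE level in 25 of 32 cases and a lower one in 2 (the same numbers adjusted over the list alone; camera adjusted p = 3.59e-05, adjusted p = 0.108 with an estimated correlation). Cholesterol synthesis genes were higher in 14 of 20 (14 adjusted over the list alone; camera adjusted p = 0.0022, adjusted p = 0.301 with an estimated correlation), glycolysis genes in 12 of 16 (15 adjusted over the list alone; camera adjusted p = 0.000522, adjusted p = 0.406 with an estimated correlation), and cytosolic heat shock proteins in 11 of 15 with 1 lower (12 and 1 adjusted over the list alone; camera adjusted p = 0.0022, adjusted p = 0.192 with an estimated correlation). Macrophage markers were higher in 17 of 28 and lower in 2 (17 and 2 adjusted over the list alone; camera adjusted p = 0.0162, adjusted p = 0.325 with an estimated correlation). With median-of-ratios scaling the numbers higher and lower were 20 and 3 for cell cycle, 13 and 2 for cholesterol synthesis, 9 and 1 for glycolysis, 8 and 1 for heat shock proteins and 13 and 4 for macrophage markers. Histone mRNAs lack poly(A) tails, and they took 0.32% of the reads of mRNA basal replicate 1, 0.0273% of basal replicate 2, and 3.52% and 4.57% of the basal footprint libraries. In the test 57 of 59 histone genes passed as higher (59 adjusted over the list alone), and Hist1h2be measured 0.88 ± 0.286 CPM in mRNA, under the value of 3 reads, and 1400 ± 217 CPM in footprints. Limma called 3148 genes higher and 1628 lower of 9412, and median-of-ratios scaling gave 2361 and 2368, which removes the excess of higher genes.

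**Figure D4:**
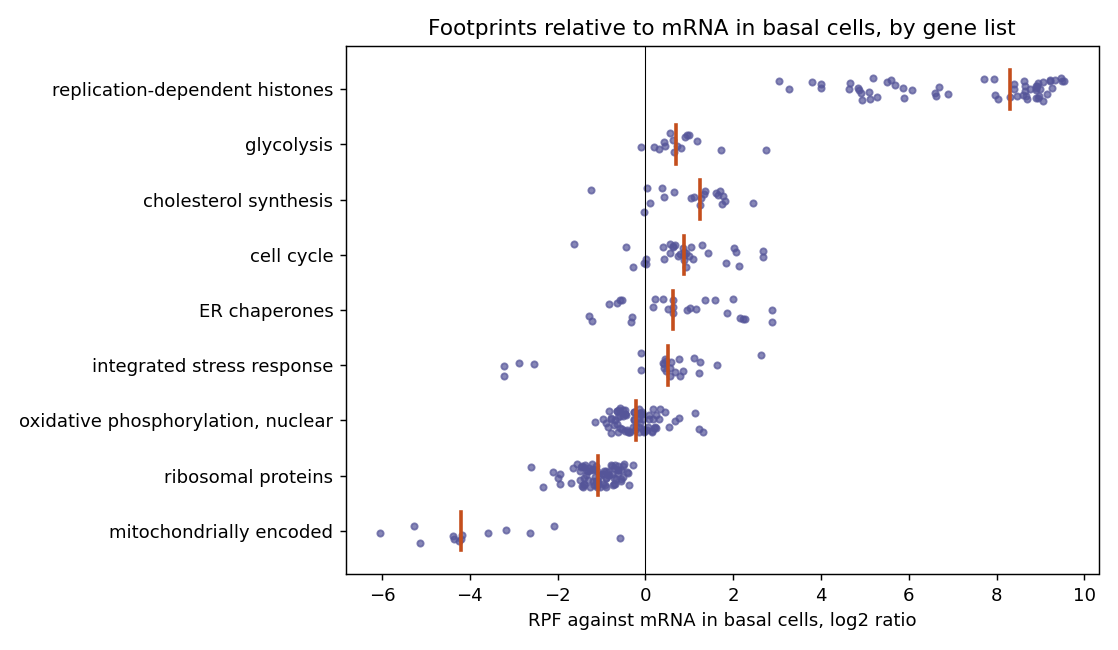
log2 ratio of RPF to mRNA in basal cells for the genes of each list; dots are genes and bars are list medians. Ribosomal proteins lie at a median of -1.08 and mitochondrially encoded genes at -4.2, both below 0 with either scaling, and histone values rest on mRNA near or under 3 reads. Mitochondrial levels may not compare with those of cytosolic mRNAs, since mitochondrial footprints can differ in length.

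For further lists some comparisons are given here. In mRNA of LPS against basal, 5 of 24 integrated stress response genes rose (8 adjusted over the list alone; camera adjusted p = 0.154), 4 of 27 ER chaperones (4 adjusted over the list alone; camera adjusted p = 0.638), 3 of 20 cholesterol synthesis genes (5 adjusted over the list alone; camera adjusted p = 0.0989) and 3 of 21 glucocorticoid induced genes (3 adjusted over the list alone; camera adjusted p = 0.452). Translation initiation factors rose in 4 of 34 cases and fell in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0989), and other TOP mRNAs, which share the regulatory start of ribosomal protein mRNAs, rose in 4 of 23 and fell in 1 (4 and 3 adjusted over the list alone; camera adjusted p = 0.154). With median-of-ratios scaling 0 of these rose and 4 fell, the median turning from 0.04 to -0.22. That scaling also left 1 integrated stress response gene higher, 2 ER chaperones higher and 1 lower, 1 cholesterol synthesis gene higher, 1 glucocorticoid induced gene higher and 2 initiation factors higher and 1 lower (median -0.28, against -0.02), and the ER chaperone median turned from 0.18 to -0.08. Interferon response genes had 0 of 10 members past limma's test (0 adjusted over the list alone) and a median of 0.03, which turned to -0.22 with median-of-ratios scaling. In mRNA of LPS + DEX against basal, 8 of 24 integrated stress response genes, 6 of 16 glycolysis genes and 9 of 32 cell cycle genes rose, with 1 cell cycle gene lower (the same numbers adjusted over the list alone; camera adjusted p = 0.433, 0.172 and 0.111). With median-of-ratios scaling 2, 3 and 3 were higher and 1, 2 and 1 lower. Histone mRNAs rose in 8 of 22 cases with LPS (5 with median-of-ratios scaling, 13 adjusted over the list alone) and in 11 with LPS + DEX (8 and 14). Camera gave them an adjusted p = 0.00368 and 0.00654, and adjusted p = 0.568 and 0.512 with an estimated correlation. Over all listed histone genes the median lay at 1.33 to 2.96 CPM in the mRNA libraries, near the value of 3 reads. Their share of reads was 0.32% and 0.0273% in the basal mRNA libraries and 0.0559% to 0.0808% after treatment, so this rise is uncertain. Among the members of the mRNA lists in this paragraph, no LPS + DEX call was kept without mRNA LPS + DEX replicate 1. Of the LPS calls of these members, only that of Ppp1r15a was kept without each mRNA LPS library. Other TOP footprints rose in 2 of 23 cases, and in 7 with median-of-ratios scaling (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.000107, adjusted p = 0.104 with an estimated correlation). Macrophage marker footprints fell in 3 of 28 cases after LPS (6 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.0454, adjusted p = 0.5 with an estimated correlation). Of the list of other cell types, Col3a1 alone is among the listed genes, so no list test was run. Its mRNA measured 3.39 and 16.2 CPM in the basal libraries, 46.7 and 51.4 CPM with LPS and 75.1 and 61.6 CPM with LPS + DEX. Its footprints measured 142 and 115 CPM, 65.1 and 60.8 CPM, and 134 and 128 CPM.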

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

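The tests of the scaling, of the shared library and of the gradient below were chosen after the results were seen. The test at equal depth was chosen before.

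Genes with reads in 1 library alone may reflect a property of that library. In mRNA basal replicate 1, 81 genes had at least 50 CPM and stayed at or under 5 CPM in the other 5 mRNA libraries, with Krt7 at 1110 CPM. Counting noise at lower depth gave at most 1 such gene in a library of fewer reads, so it does not account for them. RNA from another cell type could be present. Of 29 named markers of other cell types only Col3a1 is listed, at 3.39 CPM in that library. If every gene above a value of 16 is listed, the other markers stayed at or under 16, which argues against the cell types they mark. Cell types without a named marker are not covered, so RNA from such a type stays open.

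Ribosomal protein mRNAs were lower in both treatments than in basal cells, which is consistent with a change in their abundance or a difference in library preparation between basal and treated cells. Scaling to total reads does not account for it, since the median of LPS + DEX against basal was -0.78 with median-of-ratios scaling and -0.48 with total reads. A gradient that also separates replicates would predict -0.21 between the LPS replicates, where -0.02 was measured. That gradient is present in other genes. Over 3269 genes outside the lists, the difference between the LPS replicates had a correlation of 0.54 with LPS + DEX against basal replicate 2 (slope 0.26). Part of the mRNA difference between treated and basal cells therefore runs along an axis that also separates replicates. This limit also applies to the mRNA changes of the genes that moved in opposite directions in the 2 assays, given below. Without mRNA basal replicate 1 the median relative to all genes was -0.75, against -0.76 with it. A difference in preparation between basal and treated cells, or one that depends on transcript length, stays open.

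Footprints on mitochondrially encoded genes rose with LPS and fell with LPS + DEX, and this may come from mitochondrial translation or from how footprints were prepared. With the RPF libraries thinned to the same depth the median of LPS + DEX against LPS was -2.13, against -2.15 at full depth. Thinning keeps the expected CPM of a gene, so this shows only that counting fewer reads does not give the fall. It cannot test other properties of the shallower LPS libraries. The rise of the mitochondrially encoded genes with LPS was not tested at equal depth. Their mRNA had a median of -0.29 for LPS against basal (-0.59 to -0.04 without 1 library) where footprints had 1.44 (1.27 to 1.61), so mRNA amount does not account for the rise, while for LPS + DEX against LPS the mRNA median of -0.67 (-1.13 to -0.24 without 1 library) leaves a share in the fall open. Size selection or digestion that differed between preparations could do it, and libraries of the same group differed by at most 0.19 (log2). That does not exclude a difference between groups, since cycloheximide acts on cytosolic ribosomes and mitochondrial footprints can differ in length.

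Of the genes that passed in both assays, 85 moved in opposite directions for LPS against basal (37.2 by chance, or 79 against 18.6 with median-of-ratios scaling), but 1 such gene remained without mRNA LPS replicate 1 and 0 without replicate 2. For LPS + DEX against basal there were 39 such genes (47.2 by chance, or 39 against 30.2 with median-of-ratios scaling), and 0 without mRNA LPS + DEX replicate 1, 2 without RPF LPS + DEX replicate 1 and 4 without replicate 2.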

How the results depend on the processing

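Over the 888 values of named genes, 13634 alternative fits were made. Of these 11910 gave the same outcome, 1434 lost a call, 82 gained one, 207 moved by over 1 SE without a call and 1 reversed. The reversed value is the basal TE level of Cxcl2: 0.06 with all libraries (adjusted p = 0.926), -0.87 without mRNA basal replicate 1 (adjusted p = 0.022) and 0.99 without mRNA basal replicate 2. Tests by edgeR and DESeq2 were planned for deposited read counts and were not run on these scaled values. Scaling to total reads alone is the scale already used.

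For mRNA of LPS against basal, 994 genes passed, and 522 with median-of-ratios scaling, 390 with the replicate block, 399 with only the groups compared, 464 with limma-voom and 6 to 2179 without 1 library of the groups compared, as in all such ranges below. The labels do not say whether equal replicate numbers come from the same culture. Differences between replicates had correlations of -0.22 to 0.12 between groups over 7168 genes, so no shared replicate effect was seen. The paired fit is therefore given here only. For mRNA of LPS + DEX against LPS, 0 passed, 6 with only the groups compared and 5 without mRNA basal replicate 1. For mRNA of LPS + DEX against basal, 2106 passed, and 1 to 2875 without 1 library.

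For footprints of LPS against basal, 674 passed, 321 with only the groups compared and 375 to 709 without 1 library. For LPS + DEX against LPS, 592 passed, and 103 to 317 without 1 library. For LPS + DEX against basal, 410 passed, 619 with limma-voom and 100 to 457 without 1 library. A group left with 1 library is assumed to vary like the other groups.

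For TE of LPS against basal, 1567 passed, 870 with limma-voom and 736 to 2164 without 1 library. For LPS + DEX against LPS, 5 passed, 71 with only the groups compared, 23 with an added 5 CPM, 20 with an added 2 CPM, 25 with library weights, 52 without mRNA basal replicate 1, 0 with limma-voom and 0 to 12 without 1 library of the groups compared. For LPS + DEX against basal, 1401 passed, 864 with median-of-ratios scaling and 546 to 1895 without 1 library. Limma-voom, the added 2 CPM, library weights and the fit without mRNA basal replicate 1 were chosen after seeing the data.

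The correlation of mRNA and RPF changes for LPS + DEX against LPS went from 0.22 to 0.37 over genes with at least 30 reads in both. With the 100 genes of smallest p, the median DEX change went from 0.13 to 0.17 (mRNA higher with LPS), from -0.07 to -0.02 (mRNA lower), from -0.48 to -1.62 (RPF higher) and from 0.38 to 0.64 (RPF lower). Those 100 genes were 92 higher and 8 lower with LPS in mRNA, and 62 higher and 38 lower in RPF. Of the 190 list tests, 77 passed with camera at the preset correlation, 4 with an estimated correlation and 146 with limma's fry in either direction. With the replicate block 74 passed, and 5 list calls changed.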

Other observations

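In basal cells, single mRNAs of different function carried many footprints per mRNA read. Actb, the cytoskeletal β-actin, had a basal TE level of 3.46 ± 0.16, and Nob1 one of 2.7 ± 0.14, ahead of its loss of footprints with LPS. The cytosolic chaperone Hsp90aa1 lay at 2.54 ± 0.18. These genes were chosen after their values were seen. The amino acid exchanger Slc7a11, a target of the integrated stress response, lay at 2.64 ± 0.34, apart from Atf4 of the same list.

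Fdft1, an enzyme of cholesterol synthesis, rose in footprints with LPS from 74.9 to 191 CPM (1.34, limma) and fell again with LPS + DEX to 80.4 CPM (-1.23 ± 0.17). The connective tissue growth factor Ccn2 ran the other way, from 86 ± 29.9 CPM in basal cells to 19.4 ± 6.73 with LPS and 109 ± 0.281 with LPS + DEX. Eef2, the elongation factor that moves the ribosome along mRNA, rose in footprints with LPS + DEX against LPS (0.63), and so did the chaperone Hspa8 (0.46 ± 0.07).

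Some genes carried at least 8 times more footprint than mRNA signal, taken as means over the 6 libraries of each assay (each plus 1 CPM). Those means include the treated libraries, so a footprint change can itself place a gene in this class. The shares below are therefore partly set by the rule and do not serve as a test. Histones were not counted in the class, though the totals given here include histones. Such genes were 61 of the 8847 genes tested in footprints (0.7%), 20 of the 292 higher with LPS (6.8%) and 13 of the 382 lower (3.4%). For LPS + DEX against LPS they were 5 of the 278 higher (1.8%) and 22 of the 314 lower (7%), and for LPS + DEX against basal 10 of the 157 higher (6.4%) and 16 of the 253 lower (6.3%). Kprp, a gene of the skin barrier, had 0.763 and 0.658 CPM in basal footprints, under the value of 3 reads, and 61.5 and 79.1 CPM with LPS. It is in the class through these LPS footprints. Fragments other than those of translating ribosomes are not separated here, so single genes of this kind remain uncertain.

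The between-replicate spread was estimated at 15.2% in basal mRNA, 9.43% and 10.4% in the treated mRNA groups and 5.77% in basal footprints. For the treated footprint groups the estimate fell to its lower limit of 3.16%, so no value is given for them.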
